A study of Salmonella enterica subsp. enterica serovar Typhimurium with 9 samples.

How the data were processed

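The series holds 9 single-colour arrays of Salmonella Typhimurium on an Agilent custom design, with 3 arrays for each of 3 groups taken from the labels: untreated cells at 0 h, cells kept 2 h without ε-polylysine and cells kept 2 h with it. The labels name Cy3 as the dye in the labelling protocol. Replicates are numbered, but the labels give no pairing, so the model chosen beforehand used no pairs. Correlations of the same number between groups, looked at later, gave no sign of pairs. The design text calls the 3 experiments dependent and the labels do not say whether arrays came from separate cultures. Slide positions were taken from the file headers, which give 3 slides.

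Each deposited array file gives spot signals as intensity, background subtracted and spatially detrended, without scaling between arrays, from Feature Extraction 10.7.1.1 per the file headers. The 2 arrays of slide 1 were read without extended dynamic range and the others with it, per the file headers. The deposited flags per spot, read as 0 or 1, mark spots well above background, saturated, not uniform or outlying among replicate spots, and are of another kind than signals. The deposited series table holds log2 values that are quantile normalized over the spots, with nearly the same distribution on every array, and was used only as an alternative.

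The processed signal of each spot was put on the log2 scale and each array's 75th percentile over the 15208 spots that are not controls was subtracted. Spots flagged as not uniform or as outlying were left out (1.54% to 10.4% of spots per array), and the remaining spots of a gene were averaged. A gene counted as detected on an array when a share of at least 0.5 of its spots was well above background. Genes were kept when detected on all 3 arrays of at least 1 group, which 4186 were, and 29 with every spot flagged on an array were left out. This left 4157 of 4502 genes. The genome table at hand was of a later assembly version than the array design, so it gave gene names and neighbours only and no coordinates. It matched 4462 genes, of which 3280 have a symbol, and 40 carry only their protein identifier. No gene was saturated on every array of a group.

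Groups were compared with limma 3.58.1 in R 4.3.3, with 1 fit of all 9 arrays, moderated variances (6 residual and 3.35 prior degrees of freedom) and no block. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and all tests are two-sided. A moderated F-test took all 3 groups together. For a gene below background on every array of 1 group, the fold is given as a lower bound, computed from the level that would have been detected. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Of 45 lists with 1071 distinct members, those with fewer than 4 measured members were not tested. Changes are also given with slide as a block in the model. Because of how the groups lay, the blocked value of the polylysine group against the 0 h control is 1 array minus 1 array on slide 2, and that of the 2 h against the 0 h control uses replicate 3 of the 0 h control alone.

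The model, the scaling, the filter on detected genes, the threshold, the list tests, the lists, the comparisons and the rule for named genes were chosen before the data were examined. Leaving out flagged spots, the share of 0.5 and the lower bounds were set after the files had been read. The rule took genes with a symbol whose groups were separate: the 10 largest rises and 10 largest falls among those called for each of the first 2 comparisons and 5 and 5 for the comparison of the polylysine group with the 0 h control. It added up to 4 members with the largest called change per list described (or up to 2 as values where none was called) and 20 regulators. Of these fimZ and hilA did not pass the filter, ramA was not found by name, and the pair pmrA and pmrB was matched as basR and basS.

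The fit was tested on simulated data built from these arrays. For the polylysine group against the 2 h control it called 7.46% of genes changed by a log2 of 1, 77.6% of those changed by 2, 95.5% of those changed by 3 and 0.127% of unchanged genes. The simulated noise was independent, with 1 spread per gene for all arrays. The real groups differed in spread and arrays of a slide were correlated, so these rates need not hold for the data. A simulated slide effect alone, with an SD across genes of a log2 of 1, gave 724 called genes between the 2 h and 0 h controls without a block and 0 with it. That size was chosen and not estimated from the arrays, so 724 does not measure the real effect of slide. The effect was added to slide 3 alone, just as the block models it, so the 0 only checks the code.

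Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited table, no filter on dim genes, only genes above background on all arrays, trended and robust variances, replicate number as a block, slide as a block, only the compared groups in the fit, and each array left out in turn. The mean spot signal planned for the normexp correction is absent from the files, so the median signal and its local background were used. Chosen after seeing the data were slide 3 alone, the differences within slides 2 and 3, slide 2 left out, slide as a random block, the 2 h control averaged to 1 array, flagged spots kept, an intensity loess between arrays and the covariance of changes with the shared group's arrays divided between comparisons.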

Results

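Transcript levels were measured on 9 single-colour Agilent arrays of Salmonella Typhimurium, in 3 groups of 3 arrays each. Cells of the 0 h control were untreated. Cells of the 2 h control stood in petri dishes with soytone broth for 2 h at 30 °C, and cells of the polylysine group stood the same way with 0.001% ε-polylysine, a cationic chain of lysines used as a food preservative. Attached cells were scraped off and mixed with the planktonic cells before RNA was extracted, so each value is a mean over attached and free cells. The 75th percentile of spot signal was 715 ± 164 (SD, n = 3) in the 0 h control, 295 ± 38.4 in the 2 h control and 1356 ± 312 in the polylysine group. Of the 4502 genes on the array, between 2968 and 4415 were well above background in the 0 h control arrays, between 3662 and 3732 in the 2 h control arrays and between 4198 and 4464 in the polylysine arrays. The number of arrays limits the precision of every value.

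The arrays lay on 3 slides that did not hold the groups evenly. Slide 1 held replicates 1 and 2 of the 0 h control. Slide 2 held replicate 3 of the 0 h control and replicate 3 of the polylysine group. Slide 3 held the 3 arrays of the 2 h control and replicates 1 and 2 of the polylysine group. Across genes, which are not independent replicates, the 2 h control arrays correlated at 0.989 to 0.995, the polylysine arrays at 0.860 to 0.919, replicates 1 and 2 of the 0 h control at 0.986, and replicate 3 of the 0 h control with those at 0.872 and 0.874. The median SD of a gene on the log2 scale was 0.13 in the 2 h control, 0.46 in the 0 h control and 0.51 in the polylysine group. The first principal component held 48.0% of the variance and the second 26.6%. Because the labels do not say whether the arrays came from separate cultures, the p-values measure only the spread between these samples.

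The comparison of the polylysine group with the 2 h control asks what ε-polylysine changed in cells kept under adhesion conditions for the same time. The largest rises with polylysine included genes of envelope stress and of the PhoP-PhoQ regulon: mgtC (STM3764, a virulence factor of growth at low magnesium) was at least 77.5-fold higher (adjusted p = 0.00747), virK (STM2781, a virulence protein) at least 50.7-fold higher (adjusted p = 0.00142), and cpxP (STM4060, a periplasmic protein of the Cpx envelope stress system) rose by a log2 of 5.08 ± 0.31 (SE, adjusted p = 5.29e-05), with n = 3 arrays per group here and below. The purine synthesis gene purM (STM2499) rose by 4.52 ± 0.25 (adjusted p = 5.29e-05). The largest falls were in csgA (STM1144, the main subunit of curli fibres) at −4.50 ± 1.02 (adjusted p = 0.0153) and csgB (the curli nucleator) at −3.73 ± 1.03 (adjusted p = 0.0302). Among the next largest were narU, a nitrate transporter, at −3.73 ± 0.33 (adjusted p = 0.000416), and eutM, a shell protein of the ethanolamine microcompartment, at −3.41 ± 0.37 (adjusted p = 0.00108). The level of csgA was 2.02 ± 0.92 (SD) log2 units above the array's 75th percentile with polylysine and 6.52 ± 0.21 in the 2 h control. For mgtC the polylysine arrays read 4.00, −1.39 and 2.41, all above the 2 h control mean of −5.55 ± 0.90. The log2 changes fitted were 7.22 for mgtC and 7.16 for virK. Without replicate 1 of the polylysine group they were 6.06 and 6.55, and without replicate 2 mgtC was at 8.75. Within slide 3, where both groups lay, the differences were 6.85 for mgtC, 7.41 for virK, 4.96 for cpxP, 4.49 for purM, −4.75 for csgA, −3.84 for csgB and −3.22 for eutM. The call of csgA ended without any 1 of the 2 h control arrays or without replicate 1 of the polylysine group (adjusted p up to 0.0587), and that of csgB ended without these or replicate 3 of the polylysine group (up to 0.0992). Over all alternatives the adjusted p ranged from 0.000528 to 0.307 for csgA and from 0.000364 to 0.375 for csgB, with the highest values where the 2 h control was averaged to 1 array.

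Among the other genes with the largest rises were ybjX (STM0940) at least 48.1-fold, purT and yicE at least 21.5-fold and 16.3-fold, pagC (an outer membrane protein of the PhoP regulon) by 4.44 ± 0.89, mig-14 by 4.33 ± 0.87 and rcsA (a regulator of capsule genes) by 4.15 ± 1.15 on the log2 scale. Among those with the largest falls were yjiH and yjiG at −3.55 ± 0.51 and −3.49 ± 0.33, iadA (isoaspartyl dipeptidase) at −3.38 ± 0.27, yneA at −3.46 ± 0.59, narV (a nitrate reductase subunit) at −3.36 ± 0.66 and the plasmid virulence gene spvC at −3.16 ± 0.56. Without replicate 1 of the polylysine group rcsA was at 2.93, narV at −2.52 and spvC at −2.42, and without its replicate 2 pagC was at 5.39. The call of rcsA ended without any 1 of the 2 h control arrays or without replicate 1 of the polylysine group (adjusted p up to 0.0898). Of 17 regulators fixed beforehand that were measured, 5 passed. They were rcsA, phoQ (the PhoP-PhoQ sensor kinase) at least 5.55-fold higher, phoP (its response regulator) up by 1.23 ± 0.34, rpoH (the heat shock sigma factor) up by 1.92 ± 0.30 and rpoS (the stationary phase sigma factor) at −1.15 ± 0.26. The list of heat shock and protein folding genes did not rise with rpoH and had a median of −0.27. Leaving out any 1 array of the 2 h control ended the calls of phoP and rpoS (adjusted p up to 0.109 and 0.0719), and that of phoP also ended without replicate 1 or 3 of the polylysine group. Over all alternatives the adjusted p ranged from 0.00588 to 0.375 for rcsA, 0.00876 to 0.412 for phoP and 0.00569 to 0.376 for rpoS. The curli regulator csgD had a value of −2.25 ± 0.75 and did not pass (adjusted p = 0.0563), and the flagellar master regulators flhD and flhC had values of 0.07 and 0.03.

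In total 987 of 4157 genes passed at an adjusted p under 0.05, of which 535 rose and 452 fell, and 884 also changed at least 2-fold. Groups were separate, with the 3 values of one all above the 3 of the other, in 985 of the 987 and in 53.5% of all genes. Chance gives 10% for independent arrays. It gives a larger share if the 2 h control arrays came from 1 RNA, which is open, so 53.5% cannot be read as an excess. The rises were 54.2% of the called genes. The share was 40.6% after scaling to the array median, which moved the median of all genes to −0.16, and 20.2% of 1772 called genes after a normexp background correction, which moved it to −0.50, so changes are relative to the scale used. Averaging the 3 arrays of the 2 h control to 1 array left 4 genes called (cpxP, purM, purT and yicE), and leaving out 1 of its 3 arrays at a time left 325, 300 and 341. With that average the lone sample is assumed to vary like the other groups. Leaving out 1 array moved 33 of the 149 named genes that passed by over 1.5-fold, and 59 kept their call without any 1 array. The count was 611 without replicate 1 of the polylysine group and 1575 without replicate 3 of the 0 h control. On slide 3 alone 1366 genes were called, 844 of them among the 987 with the same sign, and with slide as a block 1655.

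The PhoP-PhoQ, PmrA-PmrB, Rcs, Cpx and sigma E, SOS and LPS lists were called as higher with polylysine. Of 19 tested members of the PhoP-PhoQ regulon, which answers low magnesium and cationic peptides, 13 rose, 0 fell and 6 did not pass (16 rose and 1 fell adjusted over the list alone), with a median log2 change of 3.01, or 2.79 with genes below background set at their bound (camera adjusted p = 1.21e-06, and adjusted p = 0.496 with an estimated correlation). In genes above background on all arrays the median was 2.79 and the call ended (adjusted p = 0.0646). Of 11 members of the PmrA-PmrB lipid A modification list, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.51 (adjusted p = 0.000905, and adjusted p = 0.496 with an estimated correlation). Its members included pmrD, the link between PhoP and PmrA, up by 2.79 ± 0.52, and yijP up by 2.48 ± 0.46. Of 26 members of the Rcs and colanic acid capsule list, 7 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 2.22, or 1.44 with bounds, and −0.01 after the normexp correction (adjusted p = 2.13e-05, and adjusted p = 0.496 with an estimated correlation). An example was ygaC, up by 3.83 ± 0.67, or by 3.03 without replicate 1 of the polylysine group. Of 21 members of the Cpx and sigma E list, 7 rose, 0 fell and 14 did not pass (8 rose and 0 fell adjusted over the list alone). The 7 were cpxP, yebE by 3.46 ± 0.57, yccA by 2.84 ± 0.32, ppiA by 2.47 ± 0.26, htrA, htpX and yqjA. The gene of sigma E itself, rpoE, did not pass, so the list call does not show that sigma E genes as such rose. The median of the list was 0.16, and −0.01 after scaling to the array median (adjusted p = 0.0141, and adjusted p = 0.169 with an estimated correlation). Of 21 SOS members, which answer DNA damage, 4 rose and 0 fell, also adjusted over the list alone, with a median of 0.83 (adjusted p = 0.0119, and adjusted p = 0.496 with an estimated correlation). Of 42 LPS core and O-antigen genes, 15 rose and 0 fell, also adjusted over the list alone, among them rfbD by 2.18 ± 0.39, with a median of 0.76 (adjusted p = 0.000324, and adjusted p = 0.496 with an estimated correlation). Within slide 3 the medians were 2.80 for PhoP-PhoQ, 1.47 for PmrA-PmrB, 2.63 for Rcs, 0.22 for Cpx and sigma E, 0.85 for SOS and 0.88 for LPS. Without replicate 2 of the polylysine group the PhoP-PhoQ median was 3.72, pmrD was at 3.39 and yebE at 4.22. Without replicate 1 the Rcs median was 1.20 and pmrD was at 2.18. The Cpx and SOS list calls ended within slide 3 (adjusted p = 0.0746 and 0.0686), and fry gave adjusted p = 0.071 for Rcs and 0.0706 for SOS. Over all alternatives the adjusted p ranged from 4.6e-08 to 0.496 for PhoP-PhoQ, 3.58e-06 to 0.496 for Rcs, 1.79e-06 to 0.169 for Cpx and sigma E and 0.00025 to 0.496 for SOS.

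The lists of curli and cellulose, which build the biofilm matrix, were called as lower with polylysine. Of 7 tested curli genes 4 fell, 0 rose and 3 did not pass (7 fell adjusted over the list alone), namely csgA, csgB, csgF at −3.16 ± 0.83 and csgG at −2.77 ± 0.68, with a median of −3.05 (camera adjusted p = 0.0016, and adjusted p = 0.496 with an estimated correlation). Of 9 cellulose synthesis genes 7 fell and 0 rose (9 fell adjusted over the list alone), with a median of −1.40 (adjusted p = 2.68e-05, and adjusted p = 0.169 with an estimated correlation). They included yaiC, a diguanylate cyclase needed for cellulose synthesis, at −2.46 ± 0.33 and yhjR at −1.90 ± 0.28. Without replicate 1 of the polylysine group csgF was at −2.37. Without its replicate 2 csgF was at −4.13 and csgG at −3.41, and without its replicate 3 cheM was at −2.13. The calls of csgF and csgG ended without any 1 array of the 2 h control or without replicate 1 or 3 of the polylysine group (adjusted p for csgF up to 0.084, and 0.00402 to 0.366 over all alternatives). Of 54 flagella and chemotaxis genes 19 fell and 3 rose (20 and 4 adjusted over the list alone). The falls included cheM, the aspartate chemoreceptor, at −2.72 ± 0.53. The median of −0.49 had a camera adjusted p = 0.0112, and adjusted p = 0.586 with an estimated correlation. Within slide 3 the medians were −2.97 for curli, −1.62 for cellulose and −0.23 for flagella and chemotaxis, whose call ended there (adjusted p = 0.184). Without replicate 1 of the polylysine group the curli median was −2.37. The flagella call also ended without replicate 3 of the polylysine group (adjusted p = 0.167), and over all alternatives the adjusted p ranged from 7.11e-07 to 0.586. Among 5 type 1 fimbriae genes 1 rose, fimH, the tip adhesin, at least 1.92-fold, and 0 fell, also adjusted over the list alone. The fimH value was −0.74 after the normexp correction, and its call ended without 1 of 6 arrays in turn, namely replicate 2 of the 0 h control, any of the 2 h control and replicates 1 and 3 of the polylysine group (adjusted p up to 0.125, and 0.0112 to 0.425 over all alternatives). The list's median was 0.16 (adjusted p = 0.735), 0.04 within slide 3, −0.01 after scaling to the array median and −0.91 after normexp. None of 29 genes of other fimbrial operons passed (median 0.25, −1.13 after normexp, camera adjusted p = 0.662).

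The ribosomal and purine lists were called as higher with polylysine, and those of stationary phase, ethanolamine and propanediol use as lower. Of 48 ribosomal protein genes 41 rose and 0 fell (45 rose and 1 fell adjusted over the list alone), among them rplA by 2.93 ± 0.35 and rpmA by 2.91 ± 0.56, with a median of 1.70 (camera adjusted p = 1.95e-18, and adjusted p = 0.249 with an estimated correlation). Of 15 purine biosynthesis genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), among them purK by 3.92 ± 0.28 and purH by 3.70, with a median of 2.96 (adjusted p = 2.82e-12). Of 17 ethanolamine genes 14 fell and 0 rose (16 and 0 adjusted over the list alone), among them eutS at −2.88 ± 0.39, with a median of −2.58 (adjusted p = 6.12e-12). Of 38 propanediol and cobalamin genes 25 fell and 1 rose (31 and 1 adjusted over the list alone), among them cbiK at −2.61 ± 0.57, with a median of −1.47 (adjusted p = 2.72e-10, and adjusted p = 0.496 with an estimated correlation). Of 27 genes of the RpoS and stationary phase list 15 fell and 1 rose (21 and 1 adjusted over the list alone), among them spvB at −2.67 ± 0.45, with a median of −1.22 (adjusted p = 1.16e-06). The calls for purine, ethanolamine and RpoS held with an estimated correlation (adjusted p = 0.00514, 0.00514 and 0.0407). They were the 3 of 28 called lists that did so. Of 7 histidine biosynthesis genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), among them hisG by 2.69 ± 0.53, with a median of 1.24 (adjusted p = 0.00297, and adjusted p = 0.496 with an estimated correlation). Leaving out replicate 2 of the polylysine group gave 3.66 for rpmA and 3.35 for hisG, leaving out its replicate 3 gave 2.07 for hisG, and leaving out its replicate 1 gave −2.06 for spvB. Within slide 3 the medians were 1.60 for ribosomal proteins, 2.89 for purine, −2.50 for ethanolamine, −1.46 for propanediol and cobalamin, −1.42 for RpoS and 0.91 for histidine. Without replicate 2 or 3 of the 2 h control the call of cbiK ended (adjusted p up to 0.0577, and 0.00282 to 0.307 over all alternatives).

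Secretion systems gave no called gene or few. None of 35 genes of the SPI-2 type III secretion system, which acts inside host cells, passed. Their median was −0.82 (camera adjusted p = 0.0389, and adjusted p = 0.777 with an estimated correlation). It was −1.58 within slide 3, where 25 of them fell, and −0.27 without replicate 2 of the polylysine group, where the list call ended (adjusted p = 0.503). The list call also ended without replicate 1 of that group (adjusted p = 0.528), without replicate 3 of the 0 h control (0.0685) and without replicate 3 of the 2 h control (0.113), and over all alternatives the adjusted p ranged from 2.41e-09 to 0.777. Of 32 genes of SPI-1, the invasion secretion system, 1 rose and 2 fell (1 and 0 adjusted over the list alone), with a median of 0.04, −0.01 within slide 3 and −0.96 after normexp (adjusted p = 0.825). The gene that rose was orgA, by 3.21 ± 0.66.

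**Figure D1:**
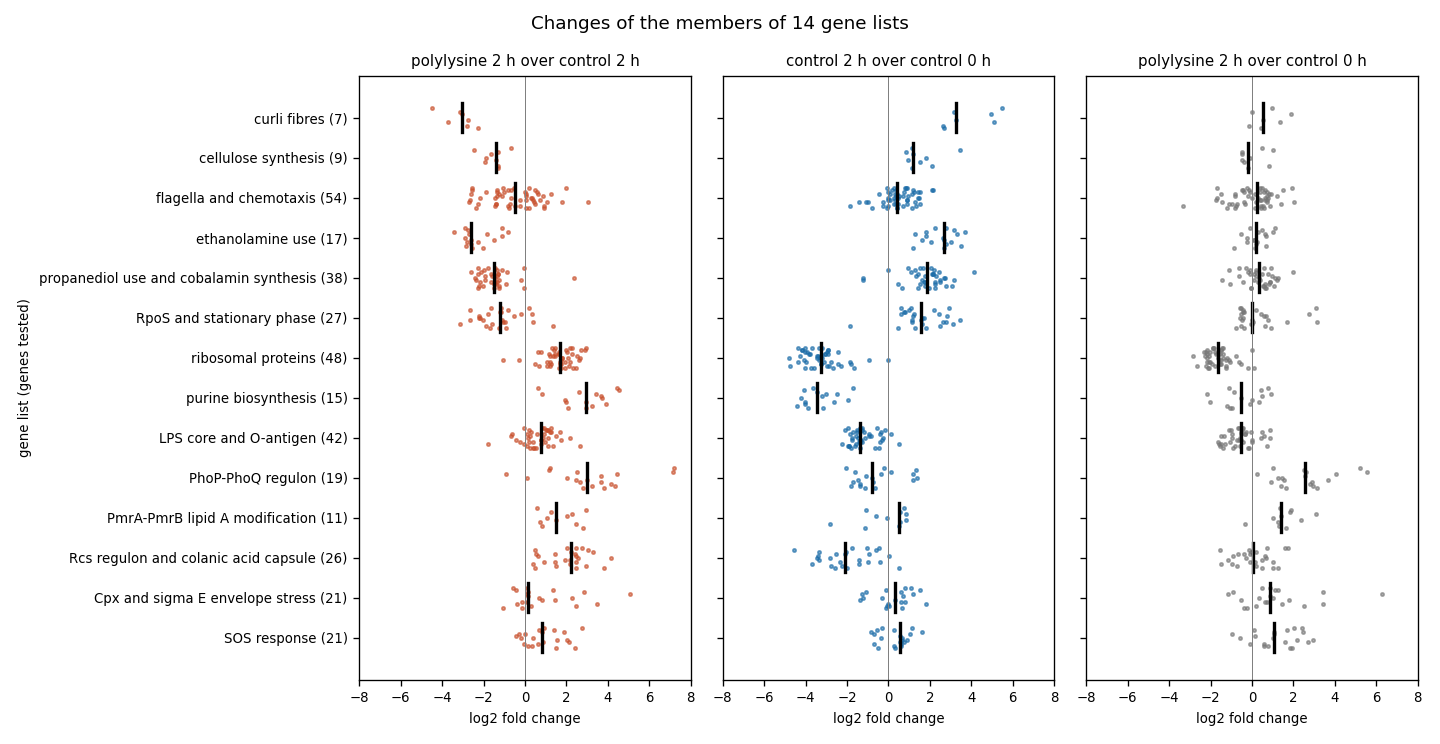
Log2 change of each tested member (dots) and the median (black bar) of 14 gene lists in the 3 comparisons, with the number of tested members in brackets. In the polylysine group against the 2 h control the medians are −3.05 for curli, −2.58 for ethanolamine, 3.01 for PhoP-PhoQ and 1.70 for ribosomal proteins, and in the 2 h control against the 0 h control they are 3.24 for curli, 2.68 for ethanolamine and −3.28 for ribosomal proteins.

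The comparison of the 2 h control with the 0 h control sets cells kept 2 h in the dishes against untreated cells at 0 h, and the labels do not say from which medium the latter were taken. The melibiose genes melB (STM4299, the permease) and melA (the galactosidase) rose by a log2 of 6.67 ± 0.67 (SE, n = 3 arrays per group, adjusted p = 0.000125) and 6.08 ± 0.69 (adjusted p = 0.000229). The curli subunit gene csgA rose by 5.48 ± 1.02 (adjusted p = 0.00303) and csgB by 5.07 ± 1.03 (adjusted p = 0.00469). The genes gabP, gabT and gabD, for uptake and use of γ-aminobutyrate, rose by 5.46 ± 0.71, 5.44 ± 0.72 and 5.24 ± 0.89. The fructose uptake gene fruF (STM2206) fell by 6.32 ± 0.62 (adjusted p = 0.000111), the gluconate kinase gene gntK was at least 45.2-fold lower (adjusted p = 0.000312), the nitrite reductase gene nirB fell by 5.18 ± 0.65 (adjusted p = 0.000366) and edd, of the Entner-Doudoroff pathway, fell by 5.00 ± 0.34 (adjusted p = 2.53e-05). The level of csgA in the 0 h control was 1.04 ± 2.46 (SD), with replicate 3 of slide 2 at 3.87 and the others at −0.14 and −0.61. No slide held both groups, and slide could be fitted as a block only through the polylysine arrays of slides 2 and 3, so each blocked value of this comparison uses replicate 3 of the 0 h control alone. Without replicate 3 of the 0 h control the changes were 5.86 for melB, 5.17 for melA, 6.89 for csgA, 6.56 for csgB, 4.71 for gabT, 4.24 for gabD, −7.01 for fruF, −6.45 for gntK and −6.05 for nirB. Without its replicate 1 they were 4.89 for csgA, 4.41 for csgB, 6.05 for gabT and 5.95 for gabD. Without its replicate 2 they were 4.65 for csgA and 4.25 for csgB. With the block the differences were 8.56 for melB, 8.04 for gabP, 3.40 for csgA (adjusted p = 0.0243), −6.08 for fruF, −2.44 for gntK (adjusted p = 0.0506), −4.07 for nirB and −5.38 for edd. Over all alternatives the adjusted p ranged from 4.23e-05 to 0.0868 for csgA and from 0.000138 to 0.0506 for gntK.

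In total 1538 genes passed, of which 822 rose and 716 fell, and 1355 changed at least 2-fold. The groups were separate in 1535 of these and in 61.3% of all genes. Chance gives 10% for independent arrays and a larger share if the 2 h control arrays came from 1 RNA. Rises were 53.4% of the called genes, and 64.5% of 1370 after normexp, which moved the median of all genes from 0.11 to 0.29. The count was 1411 with slide as a block, 955 of them among the 1538, and 262 with the 2 h control averaged to 1 array. It was 994, 976 and 1019 without each array of the 2 h control in turn. Leaving out 1 array moved 35 of the 166 named genes that passed by over 1.5-fold, and 129 kept their call without any 1 array. Of the 17 measured regulators 6 passed. The curli regulator csgD rose by 2.67 ± 0.75 (adjusted p = 0.0214), or by 3.44 without replicate 3 of the 0 h control, with a blocked value of 1.45 (adjusted p = 0.42). The envelope stress sigma factor gene rpoE rose by 1.54 ± 0.29 and the flagellar sigma factor gene fliA by 1.32 ± 0.34. The blocked value of fliA was 0.11 (adjusted p = 0.883), and its call also ended without replicate 2 of the 0 h control or replicate 1 or 2 of the 2 h control (adjusted p up to 0.062, and 0.00316 to 0.883 over all alternatives). The call of csgD also ended without replicate 1 or 2 of the 0 h control or any 1 array of the 2 h control (adjusted p up to 0.0691, and 0.00396 to 0.42 over all alternatives).

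The lists of curli, cellulose, ethanolamine, propanediol and cobalamin, RpoS, fatty acid degradation and the TCA cycle were called as higher at 2 h than at 0 h. Of 7 curli genes 7 rose, also adjusted over the list alone, with a median of 3.24 (camera adjusted p = 0.00434, and adjusted p = 0.66 with an estimated correlation). The curli median was 4.09 without replicate 3 of the 0 h control. With slide as a block it was 1.45, 2 genes rose and the list call ended (adjusted p = 0.108, and 0.000107 to 0.66 over all alternatives). Of 9 cellulose genes 7 rose and 0 fell, also adjusted over the list alone, with yaiC up by 3.47 ± 0.33 and a median of 1.18 (adjusted p = 0.00134, and adjusted p = 0.273 with an estimated correlation). Of 17 ethanolamine genes 15 rose and 0 fell (16 and 0 adjusted over the list alone), with eutM up by 3.70 ± 0.37 and a median of 2.68 (adjusted p = 6.23e-09). Of 38 propanediol and cobalamin genes 28 rose and 0 fell (30 and 1 adjusted over the list alone), with pduJ up by 4.13 ± 0.43 and a median of 1.85, or 1.77 with bounds (adjusted p = 1.87e-08, and adjusted p = 0.613 with an estimated correlation). Of 27 RpoS and stationary phase genes 19 rose and 1 fell, also adjusted over the list alone, with spvC up by 3.11 ± 0.56 and a median of 1.58 (adjusted p = 1.85e-06). Of 7 fatty acid degradation genes 6 rose and 0 fell, also adjusted over the list alone, with fadA up by 5.04 ± 0.71 and a median of 2.97 (adjusted p = 0.00254, and adjusted p = 0.66 with an estimated correlation). Of 19 genes of the TCA cycle and glyoxylate shunt 12 rose and 1 fell (15 and 1 adjusted over the list alone), with acnA, an aconitase, up by 3.14 ± 0.37 and a median of 1.96 (adjusted p = 0.000131, and adjusted p = 0.633 with an estimated correlation). The value of fadA was 5.72 without replicate 1 of the 0 h control and 4.12 without replicate 3. With slide as a block the medians were 1.58 for cellulose, 2.55 for ethanolamine, 2.17 for propanediol and cobalamin, 2.56 for RpoS, 4.34 for fatty acid degradation and 2.62 for the TCA cycle.

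The ribosomal protein, purine, LPS and Rcs lists were called as lower in the same comparison. Of 48 ribosomal protein genes 46 fell and 0 rose (47 fell adjusted over the list alone), with rpsN at −4.83 ± 0.35 and a median of −3.28 (camera adjusted p = 2.98e-30, and adjusted p = 0.155 with an estimated correlation). All 15 purine biosynthesis genes fell, also adjusted over the list alone, with purG at −4.43 ± 0.36 and a median of −3.47 (adjusted p = 4.53e-12). Of 42 LPS core and O-antigen genes 23 fell and 0 rose (26 and 0 adjusted over the list alone), with rfbF at −2.09 ± 0.25 and a median of −1.37 (adjusted p = 1.46e-08, and adjusted p = 0.191 with an estimated correlation). Of 26 Rcs and capsule genes 13 fell and 0 rose, also adjusted over the list alone, with wcaG at least 7.83-fold lower and a median of −2.09, or −1.53 with bounds (adjusted p = 0.000124, and adjusted p = 0.709 with an estimated correlation). The Rcs call ended in genes above background on all arrays (−2.52, adjusted p = 0.0529) and with fry (adjusted p = 0.0833, and 4.7e-08 to 0.709 over all alternatives). The nucleoid protein gene fis, whose protein marks fast growth, fell by 4.55 ± 0.25 (adjusted p = 1.81e-05). Of 19 called lists the calls for purine, ethanolamine and RpoS held with an estimated correlation (adjusted p = 0.01, 0.0117 and 0.0457). With slide as a block the medians were −2.83 for ribosomal proteins, −3.14 for purine, −1.82 for LPS and −4.21 for Rcs. Iron uptake (7 of 30 fell, none rose, also adjusted over the list alone, median −0.82, adjusted p = 0.0151, and adjusted p = 0.751 with an estimated correlation) depended on replicate 3 of the 0 h control, without which the median was −0.11 (adjusted p = 0.497, and 1.2e-05 to 0.751 over all alternatives). The blocked median, in which that replicate is the only 0 h array that counts, was −2.28 and is not separate evidence.

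The comparison of the polylysine group with the 0 h control shows how treated cells differed after 2 h from the starting cells. The envelope stress gene cpxP rose by a log2 of 6.28 ± 0.31 (SE, n = 3 arrays per group, adjusted p = 2.18e-05), virK by 5.57 ± 0.86 (adjusted p = 0.00316), mgtC by 5.19 ± 1.33 (adjusted p = 0.0279), and the melibiose genes melA and melB by 4.83 ± 0.69 and 4.83 ± 0.67. The lysine-cadaverine antiporter gene cadB fell (−4.97 ± 0.79, adjusted p = 0.00359), as did edd (−4.78 ± 0.34, adjusted p = 0.000133), nirB (−4.57 ± 0.65, adjusted p = 0.00231), gntK (−4.40 ± 0.72, adjusted p = 0.00402) and ygbK (−4.18 ± 0.58, adjusted p = 0.00214). On slide 2, which held 1 array of each group, the differences were 6.21 for cpxP, 2.86 for virK, 3.87 for mgtC, 6.57 for melA, 6.63 for melB, −3.46 for cadB, −4.91 for edd, −3.25 for nirB and −1.73 for gntK. Without replicate 3 of the 0 h control the changes were 6.67 for virK, 3.92 for melA, 4.01 for melB, −5.78 for cadB, −5.44 for nirB and −4.99 for gntK. Without its replicate 2 virK was at 4.91. Without replicate 1 of the polylysine group virK was at 4.95 and cadB at −4.29. Without replicate 2 of that group cadB was at −5.70, and without its replicate 3 gntK was at −5.13 and ygbK at −3.58. The value of mgtC was 4.03 without replicate 1 of the polylysine group, 6.72 without its replicate 2, and 4.33 and 6.22 without replicates 1 and 3 of the 0 h control. The call of mgtC ended without replicate 1 or 2 of the 0 h control or replicate 1 or 3 of the polylysine group (adjusted p up to 0.0953, and 0.00428 to 0.279 over all alternatives). No curli gene was called: the curli regulator csgD had a value of 0.42 (adjusted p = 0.729) and csgB of 1.35 (adjusted p = 0.391), and csgA differed at −1.35 on slide 2.

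In total 716 genes passed, of which 383 rose and 333 fell, and 660 changed at least 2-fold. The spread was pooled with the 2 h control, whose median SD was 0.13 against 0.46 and 0.51 in the 2 compared groups. The SEs and p-values of this comparison are thus likely too small, and its count too high. The groups were separate in 706 of these and in 29.1% of all genes, where chance gives 10% for independent arrays. Rises were 53.5% of the called genes, and 31.5% of 851 after normexp, which moved the median of all genes from 0.10 to −0.26. With slide as a block 777 genes were called, 354 of them among the 716, but each blocked value of this comparison is the slide 2 difference of replicate 3 of each group, 1 array against 1, with a spread assumed from the other arrays. With only these groups in the fit 208 were called. Averaging the 2 h control to 1 array gives the same fit for this comparison, so it is not a separate check. The count was 330 without replicate 2 of the 0 h control, 402 without replicate 1, 1208 without replicate 3, and 465, 465 and 475 without each array of the 2 h control in turn. Leaving out 1 array moved 39 of the 123 named genes that passed by over 1.5-fold, and 67 kept their call without any 1 array. Of the 17 regulators 4 passed, among them rpoH up by 1.46 ± 0.30 and basR, the PmrA response regulator, up by 1.37 ± 0.27. The heat shock and protein folding list did not rise with rpoH here either, with a median of −1.08.

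Against the 0 h control the PhoP-PhoQ, PmrA-PmrB, Cpx and sigma E, SOS and branched-chain amino acid lists were called as higher, LPS as lower and Rcs was not called. Of 19 PhoP-PhoQ members 9 rose and 0 fell (14 and 0 adjusted over the list alone), with pagK up by 3.68 ± 0.73 and a median of 2.56 (camera adjusted p = 7.82e-06, adjusted p = 0.576 with an estimated correlation, and adjusted p = 0.0541 with fry). Of 11 PmrA-PmrB members 4 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.38 (adjusted p = 0.00188, and adjusted p = 0.657 with an estimated correlation), which was 0.52 with slide as a block, where the call ended (adjusted p = 0.13). Of 21 Cpx and sigma E members 10 rose and 0 fell (11 and 1 adjusted over the list alone), with yccA up by 3.43 ± 0.32 and a median of 0.87 (adjusted p = 0.00155, and adjusted p = 0.287 with an estimated correlation). Of 21 SOS members 8 rose and 1 fell (13 and 1 adjusted over the list alone), with sulA, a division inhibitor, up by 2.70 ± 0.48 (3.35 without replicate 2 of the polylysine group) and a median of 1.07 (adjusted p = 0.00155, and adjusted p = 0.576 with an estimated correlation). Of 15 branched-chain amino acid biosynthesis genes 9 rose and 0 fell (12 and 0 adjusted over the list alone), with ilvC up by 3.24 ± 0.55 and a median of 1.38 (adjusted p = 0.00024, and adjusted p = 0.576 with an estimated correlation). The PhoP-PhoQ median was 1.84 without replicate 1 of the polylysine group, and pagK was at 2.99 and 4.38 without replicates 1 and 3 of the 0 h control and at 4.37 without replicate 2 of the polylysine group. Of 26 Rcs and capsule genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of 0.03, which was −0.20 after normexp and −1.17 with the block, and the test's direction was down (adjusted p = 0.683). Of 42 LPS genes 5 fell and 0 rose, also adjusted over the list alone, with a median of −0.54 (adjusted p = 0.000596, and adjusted p = 0.576 with an estimated correlation). The LPS call ended with normexp (−0.59, adjusted p = 0.082) and with fry (adjusted p = 0.0516, and 4.98e-05 to 0.576 over all alternatives). With slide as a block the medians were 1.70 for PhoP-PhoQ, 0.91 for Cpx and sigma E, 0.96 for SOS, 1.91 for branched-chain amino acids and −1.05 for LPS. The histidine list, with a median of 0.68, was not called against the 0 h control (adjusted p = 0.171). Over all alternatives the adjusted p ranged from 1.38e-07 to 0.576 for PhoP-PhoQ and from 9.08e-06 to 0.657 for PmrA-PmrB.

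The list of ribosomal protein genes was called as lower than in the 0 h control. Of 48, 39 fell and 0 rose (43 fell adjusted over the list alone), with rplI at −2.65 ± 0.36 and a median of −1.65 (camera adjusted p = 7.04e-25, and adjusted p = 0.287 with an estimated correlation), and −1.22 with slide as a block. Of 35 SPI-2 genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of −1.86 (adjusted p = 4.8e-08, adjusted p = 0.657 with an estimated correlation, and adjusted p = 0.137 with fry), and −0.91 with slide as a block. The SPI-2 median was −1.28 without replicate 2 of the polylysine group and −2.80 without replicate 3. None of 7 curli genes passed (median 0.51, adjusted p = 0.683), where the slide 2 difference had a median of −1.40. The curli gene csgC had a value of 1.91 (adjusted p = 0.351) and a slide 2 difference of −1.97, which is 1 array minus 1 array. Of 9 cellulose genes 1 rose (0 adjusted over the list alone), and the list's median of −0.20 and its mean of 0.02 differed in sign (adjusted p = 0.981). None of 17 ethanolamine genes passed (median 0.19, −0.48 after normexp, adjusted p = 0.483). Of 15 purine genes 1 rose and 6 fell (2 and 6 adjusted over the list alone), with a median of −0.53 (adjusted p = 0.0865). None of the 21 called lists held with an estimated correlation.

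**Figure D2:**
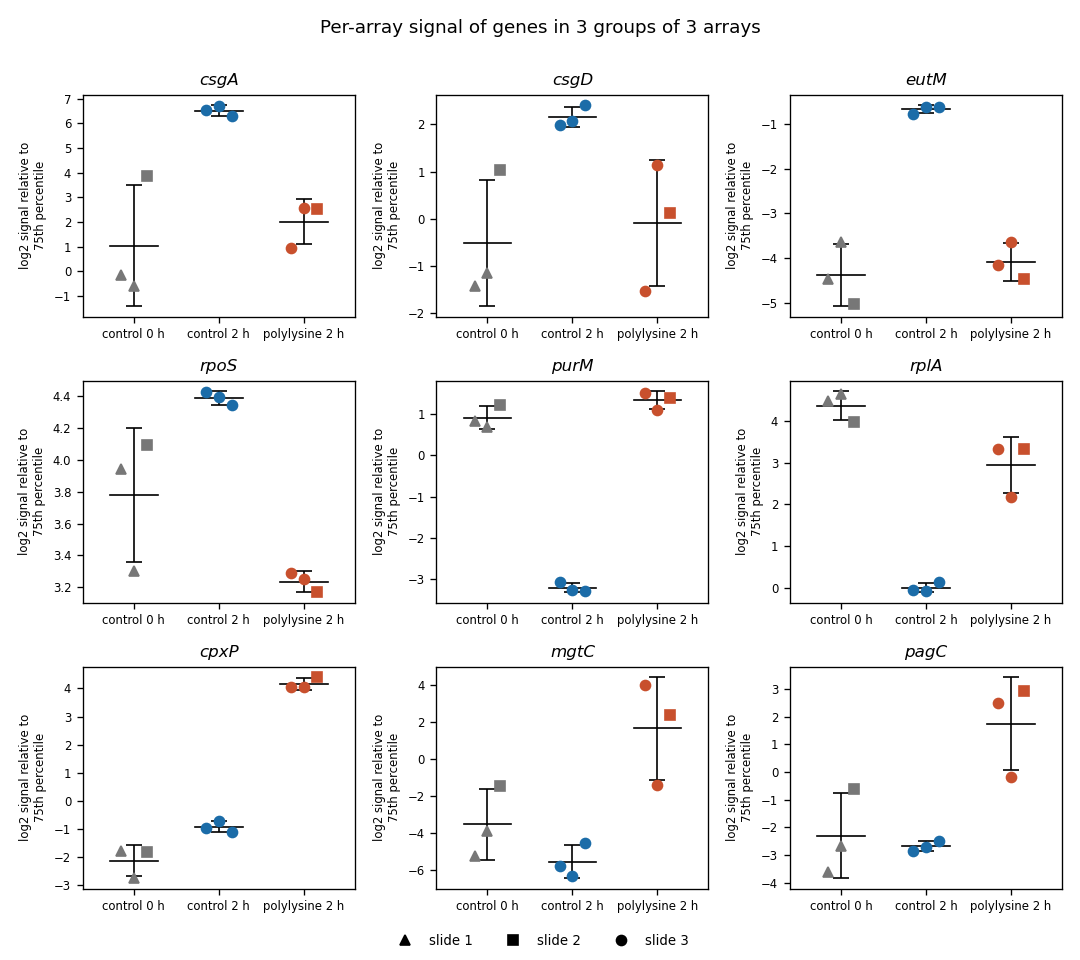
Log2 level relative to the array's 75th percentile of 9 genes on each of the 9 arrays, with the marker shape giving the slide and the bar and error the mean ± SD of 3 arrays. For csgA the 2 h control arrays stand at 6.29 to 6.71 and the polylysine arrays at 0.96, 2.57 and 2.52, while for cpxP the polylysine mean is 4.16 ± 0.20 and the 2 h control mean −0.92 ± 0.20.

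The comparisons share groups, so their changes are linked by design. Of the genes that fell from the 0 h to the 2 h control, 328 were higher with polylysine than in the 2 h control, and of those that rose 338 were lower, where independent calls would give 92.2 and 89.4. In both comparisons 5 genes rose and 2 fell. The covariance of these changes across genes was −1.10, where groups with no differences but the shared arrays gave −0.0998 in 100 simulations of independent arrays. The changes correlated at −0.672, where the simulations gave −0.499. Of the genes called against the 0 h control in both other groups, 213 rose in both and 269 fell in both, where independent calls would give 75.7 and 57.4. Their covariance across genes was 0.902 above the simulated one. With polylysine, 97 genes stood above both controls and 24 below both, where independent calls would give 49.3 and 36.2, and the changes correlated at 0.145 across genes where the shared arrays alone gave 0.501. With the shared arrays divided between the comparisons, in each of 6 ways, the covariance ranged from −1.11 to −1.07 for polylysine against the 2 h control with the 2 h against the 0 h control, from 0.453 to 1.02 for the changes against the 0 h control, and from −0.189 to 0.256 for the changes with polylysine. This division was chosen after the other values were seen, and it does not remove a deviation common to all 3 arrays of the shared group. In the test across all 3 groups, 1719 genes passed, and 271 with the 2 h control averaged to 1 array. Without each array of the 2 h control in turn 987, 970 and 1003 passed.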

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

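Chosen only after the results were seen were the tests on slide 3 alone, with slide 2 left out, with slide as a random block, with the 2 h control averaged to 1 array, with flagged spots kept and with an intensity loess. Quantile normalization, trended and robust variances, no filter on dim genes, flagged spots kept and the intensity loess moved none of the called counts below by over 1.5 times. The brightest-probe alternative was not run, as each gene had 1 probe. Signal over background limits the dim genes: 71 called folds in the polylysine group against the 2 h control, 90 in the 2 h control against the 0 h control and 1 in the polylysine group against the 0 h control are lower bounds. For effects of slide, scaling and correlation below and for the arrays left out, the cause was not tested. Under a slide block, polylysine against the 0 h control is 1 array against 1 and the 2 h against the 0 h control uses 1 array of the latter.

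The 987 genes of polylysine against the 2 h control became 1772 with normexp, 1655 with slide as a block and also with slide 2 left out, 1555 with slide as a random block and 4 with the 2 h control averaged. With it averaged the 1538 of the 2 h against the 0 h control became 262, the 716 of polylysine against the 0 h control 208 and the 1719 of the F-test 271. The 716 became 208 with only the compared groups in the fit and 1285 with slide 2 left out. For polylysine against the 0 h control, only the compared groups and the averaged 2 h control are the same fit. For polylysine against the 2 h control, slide as a block and slide 2 left out are likewise the same fit. With 1 array left out the counts ranged over 300 to 1575, 976 to 1709, 330 to 1208 and 970 to 2283 for the F-test. The 28, 19 and 21 called lists became 3, 3 and 0 with an estimated correlation, and fry called 8 lists in the last comparison. With 1 array left out they ranged over 25 to 29, 15 to 19 and 16 to 23.

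In polylysine against the 2 h control, an estimated correlation ended the calls of curli (−3.05, adjusted p = 0.496), cellulose (−1.40, 0.169), PmrA-PmrB (1.51, 0.496), PhoP-PhoQ (3.01, 0.496) and flagella (−0.49, 0.586). The PhoP-PhoQ call also ended in genes above background on all arrays (2.79, 0.0646). The flagella call ended with fry (−0.49, 0.146), with slide as a block or slide 2 left out (−0.23, 0.16) and on slide 3 alone (−0.23, 0.184). With 1 array left out the medians ranged over −3.55 to −2.37 for curli, −1.69 to −1.16 for cellulose, −0.04 to 0.45 for type 1 fimbriae, −0.78 to −0.23 for flagella, 2.54 to 3.72 for PhoP-PhoQ and 1.34 to 1.79 for PmrA-PmrB.

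Directions turned as follows, where the value was called under at least 1 of the settings compared. With normexp in polylysine against the 2 h control, emrB was −0.60, fimH −0.74, pduX −0.16, pyrF −0.32, stbD −0.87, trpD −1.06 and the other fimbrial operons −1.13. Under it the medians of more lists changed sign with no turned call: Rcs from 2.22 to −0.01, phosphate starvation from 0.99 to −0.10, multidrug efflux from 0.82 to −0.04, iron uptake from 0.28 to −1.01, type 1 fimbriae from 0.16 to −0.91 and SPI-1 from 0.04 to −0.96. With normexp in the 2 h against the 0 h control, invJ was 0.21, kdpB 0.38 and trpD 0.13, and in polylysine against the 0 h control pduL was −0.0448. With slide as a block in the 2 h against the 0 h control, flagella were −0.50, SPI-2 0.92 and hisI 0.95. With that block in polylysine against the 0 h control, arginine biosynthesis was 1.71, csgC −1.97 and glycolysis 0.10. There the camera direction turned for heat shock and phosphate starvation, while their medians of −0.22 and 0.18 kept their sign. In that comparison hilD was 0.64 with slide 2 left out and −0.41 to 0.64 with 1 array left out, and arginine biosynthesis −0.78 to 1.25.

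Of 149 called named genes in polylysine against the 2 h control, 145 lost their call and kept their direction with the 2 h control averaged, 80, 85 and 87 without each array of it in turn, 20 with normexp and 8 with slide as a block. Of 166 in the 2 h against the 0 h control 43 did so with slide as a block, and of 123 in polylysine against the 0 h control 50.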

Other observations

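The tests of slide for the polylysine group against the 2 h control, of array brightness, of a single RNA source, of shared arrays and of 0 h RNA, and the tests of overlap with lists, were chosen only after the results were seen.

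Some genes stood outside the range of both controls with polylysine. The 97 genes higher with polylysine than in the 2 h and the 0 h control (n = 3 arrays each) held 8 of 19 PhoP-PhoQ members (Fisher's exact test, one-sided, adjusted p = 1.81e-07 over 45 lists), 7 of 21 Cpx and sigma E members (adjusted p = 6.07e-06) and 6 of 15 branched-chain amino acid genes (adjusted p = 8.76e-06). This test treats genes as independent, and with an estimated correlation the camera tests against the 2 h and the 0 h control gave adjusted p = 0.496 and 0.576 for PhoP-PhoQ, 0.169 and 0.287 for Cpx and sigma E, and 0.496 and 0.576 for branched-chain amino acids. The branched-chain call against the 2 h control also ended with slide as a block (adjusted p = 0.0646), on slide 3 alone (0.0692) and without replicate 3 of the polylysine group (0.0538). Examples chosen after their values were seen were mgtA, a magnesium transporter, at 4.14 and 2.78 against the 2 h and the 0 h control, and ycfS at 2.69 and 2.88. The 24 genes lower than both controls held 3 of 20 aerobic respiratory chain genes (adjusted p = 0.00814), of which cydA and cydB are neighbours, and camera gave adjusted p = 0.496 and 0.673 for this list with an estimated correlation and fry 0.0502 and 0.245. The aerobic chain median against the 0 h control was −0.68 over all arrays and −0.30 on slide 2, which is 1 array minus 1 array. The list of anaerobic respiration and fermentation was not enriched among the 24 genes (2 of 61, adjusted p = 0.535). Single genes chosen after their values were seen were pflB, pyruvate formate-lyase, at −2.07 and −2.63, focA, a formate channel, at −1.83 and −2.52, and adhE, the alcohol dehydrogenase, at −1.84 and −2.61. Both sets use the same polylysine arrays.

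Runs of neighbouring genes outside the fixed lists also moved together with polylysine against the 2 h control, and these were chosen after their values were seen. The 5 genes from sufA to sufS, which build iron-sulfur clusters, fell with a median log2 of −1.86. The 5 genes from glgP to glgB, of glycogen metabolism, fell with a median of −1.61, and 4 genes from gabT to ygaU, which include gabT and gabP of γ-aminobutyrate use, with a median of −2.62. With them fell the 7 genes from STM3254 to STM3260, which include sugar transport genes, with a median of −2.52. The 5 genes from rsmC to prfC rose with a median of 1.70, and the 4 from queA to secD, which include a protein export gene, with a median of 1.79. From the 0 h to the 2 h control all these genes were called in the other direction. Medians there were 1.53 for sufA to sufS, 1.83 for glgP to glgB and −2.64 for rsmC to prfC. The others lay in longer runs, at 5.23 (tctE to yqaE), 5.42 (STM3251 to STM3262) and −2.45 (queA to secF). With polylysine the run from STM3251 to STM3261 still stood above the 0 h control, by a median of 3.35.

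The 987 genes called with polylysine against the 2 h control came from arrays that differed in slide and brightness. The tables argue against slide as the whole cause, since 844 were called with the same sign on slide 3 alone. They argue against a scale that varies with intensity as the whole cause, since 917 were after an intensity loess. The loess cannot undo background effects in the dim 2 h control arrays. With a normexp background correction 766 of the 987 were called in either direction, a looser count than the 2 before. Rises were 20.2% of its 1772 called genes against 54.2%, so such effects stay open. Of the 10 splits of the 6 arrays 1, the real one, gave 987 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. It stays open whether the 3 arrays of the 2 h control came from 1 RNA. Their between-array variance was 1.67 to 3.13 times the spot variance. The ratio was 3.62 for the 0 h control arrays of slide 1 and 133 for the polylysine arrays of slide 3. The 2 h control arrays thus differed far less than the polylysine arrays of the same slide, and the p-values against this group depend on the answer. No biological explanation was tested beyond the group itself, which stays open.

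The 1538 genes called between the 2 h and 0 h controls came from arrays that shared no slide. The tables argue against a difference between slides 2 and 3 as the whole cause. Over these genes the polylysine arrays of slide 3 minus that of slide 2 differed by a median of −0.166 in the direction of the change. The 2 h control minus the slide 2 array of the 0 h control differed by 1.84. This rests on 1 polylysine array of slide 2. It cannot test slide 1, which held 2 arrays of the 0 h control and no other group and was read without extended dynamic range. A simulated slide effect alone gave 724 called genes in this comparison. Its size was chosen and not estimated from the arrays, so 724 does not say how many of the 1538 depend on slide. Of the 10 splits of the 6 arrays 1, the real one, gave 1538 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. An effect of slide on single genes stays open, as do time, medium, temperature and contact with the dish, which the design does not separate.

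Most genes called in both comparisons reversed with polylysine the change seen from 0 h to 2 h. For arrays taken as independent, the covariance was 11.1 times the simulated one. This argues against the shared arrays of the 2 h control as the whole cause. The simulation drew each array separately, so it cannot decide this if the 2 h control arrays came from 1 RNA. RNA kept from 0 h in a fixed share of the cells is argued against as the only change. The share fitted was 0.74 in genes that rose and 0.348 in genes that fell, a difference of 0.392. The bootstrap range of 0.336 to 0.433 resampled genes as if independent and does not measure the spread between arrays. For single polylysine arrays the shares were 0.703 to 0.773 and 0.283 to 0.397. The genes were picked by calls on the same control arrays. Equal shares would need an overall log2 scale of −0.719, while 691 genes alike in both controls stood at 0.141. This test was first run on genes changed at least 4-fold, with shares of 0.796 and 0.254, and then on all called genes. The open question on the 2 h control arrays bears on this pattern too, and no biological explanation of it was tested.

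For the polylysine group against the 0 h control, 1 of 10 splits, the real one, gave 716 genes and the highest other gave 231, and 10 splits are too few for a share under 0.05. In the test across all groups, 1 of 100 drawn splits, the real one with 1719 genes, gave as many, and the highest other gave 1360, so chance is excluded at a share under 0.05 for arrays taken as independent. The splits do not account for slides or for 1 RNA behind the 2 h control arrays, and 271 genes were called with those arrays averaged.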
